A study of Sus scrofa with 7 samples.

How the data were processed

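RNA-seq had been made from the hypothalamus of 4 control and 3 antibiotic piglets. Per the labels' protocols, the tissue was flash frozen, RNA was extracted with Trizol, libraries were built with an Illumina TruSeq RNA kit from 1 ug of total RNA, and sequencing used an Illumina HiSeq 2000. Groups were taken from the sample titles. The treatment protocol names a randomized complete block design for 12 piglets, and the labels do not tie library numbers to blocks. The submitters' processing notes list Bowtie 0.12.2 and the genome names susScr3 and mm8, without a role for either. The aligner settings, the annotation and the counting of strand are not given in the sources used here.

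The authors deposited 3 sheets of 1 workbook. Per the file headers, the first holds 1 FPKM value per gene and group (fragments scaled to transcript length and to all mapped fragments), and how the libraries were combined and scaled is not given in the sources used here. The deposited log2 fold is the antibiotic over the control FPKM with no pseudocount, and it differed by more than 0.01 from the ratio of the printed values in 16 of 15886 features with both values above 0, among them AQP4 and SLC6A17. The deposited p-value has a smallest value of 5e-05, shared by 2081 tested features, and the authors' q-value there is 0.000336, so those features cannot be ranked by p. The authors' test statistic, a score, has the opposite sign to the fold in nearly all tested features and was not used. The layout and column names are those of a Cuffdiff gene test, but no source used here names that program. The significant column of the deposited table was checked to equal a q under 0.05 with an absolute log2 fold of at least 1 in every row. The second sheet repeats the 2111 significant features and the third holds 1389 of them.

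The deposited table had 16991 features after 6 blank rows were left out, and 13352 had been tested by the authors. No column held the values of a single library, so the depth of each library is unknown, no interval for a value could be computed, and the authors' q carries all the replicate error in the text. The limma test planned before the data were examined, its gene set tests, leaving out single libraries, blocking, weights and other splits of the libraries all need a value per library and could not be run. Genes were called changed from the authors' q, at a threshold of 0.05. The p-values then measure the spread between these animals' libraries only as far as the authors' test used it, which the sources used here do not describe.

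There were 27 gene lists fixed before the data were examined, covering monoamines and their receptors, other transmitters, synaptic vesicles, peptides, hormone receptors, neurotrophins, early genes, amino acid transport, kynurenine enzymes, cytokines, interferon, stress, ribosomes, respiration and the cell types of a hypothalamus block. Of their 707 symbols 575 were matched to a row, 49 of these only through the Ensembl ID and the gene name table, and of several rows the tested one with the highest mean FPKM was used. For each list the members past the threshold were counted, again with the p-values adjusted over the list alone by the Benjamini-Hochberg method. The list median was placed among 10000 random lists drawn from the tested genes in 20 bins of mean FPKM. This placing is a description of 2 columns of values and not a test between animals. Tested on simulated data, lists of 20 of 13339 genes lay outside the central 95% in 4% of draws with no shift, and 55.5% of lists shifted by 0.5 log2 and 98.5% of lists shifted by 1 lay above it. The simulated lists were drawn at random from folds permuted within bins, so their members did not move together. Genes of a real list can move together, and these rates need not hold for such lists.

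The rule for named genes was also fixed in advance. It took the 10 largest rises and falls among significant features with a gene symbol and a mean of at least 1 FPKM, 25 transmitter and peptide genes whatever their values, of which 22 were matched, and the 4 members of each list with the smallest p. Ties in p were broken by the larger absolute fold, and the rule's demand that libraries of the groups do not overlap could not be applied. Some genes that this rule takes are not reported here. Coordinates are those of the deposited table. Gene synonyms and neighbours were read from the RefSeq gene table of the assembly Sscrofa11.1, from which no coordinates were taken. A further list of midbrain and raphe regulators, one of hindbrain genes and a definition of small structural RNAs were written after the table had been read and before their values were looked at.

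Alternatives recomputed the 2-fold calls and the list medians after scaling each group to its upper quartile, trimmed mean scaling, quantile normalization, pseudocounts of 0.1 and 1, a minimum of 5 FPKM in a group and a q of 0.01. Alternatives chosen after seeing the data were a pseudocount of 0.5, a minimum of 1 FPKM in both groups, a recomputed adjustment, leaving out loci of 1000 bases or less with small structural RNAs and mitochondrial rows, and leaving out rows that overlap another row. List percentiles under alternatives used 2000 random lists. KEGG terms came from the deposited table, and the 191 terms with at least 15 tested genes were placed among random lists in the same way. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, with figures drawn by matplotlib 3.10.9.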

Results

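The series compared the hypothalamus of piglets given antibiotics into the distal ileum with that of piglets given saline. The hypothalamus is the brain region that controls feeding, body temperature and hormone release. The piglets were Duroc x Landrace x Large White crosses aged 45 postnatal days and carried a T-cannula, a fixed tube that opens into the distal ileum. Controls received 10 mL of saline, and the antibiotic group received the same volume with ampicillin at 150, gentamicin at 4 and metronidazole at 30 mg per kg per day. RNA-seq libraries were made from 4 control and 3 antibiotic hypothalami, and 12 piglets had been randomised. The series title names the expression of neurotransmitters in the hypothalamus as its subject.

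The authors' deposited table held 1 FPKM value per gene and group, so no spread between animals could be computed and the depth of each library was unknown. Every FPKM, fold, p and q below is taken from that table, and only the authors' p and q could hold replicate error. How far they do is unknown, because the sources used here do not describe how the libraries entered the authors' test. In what follows, a gene rose or fell where the authors' q was under 0.05, and "median log2" is the median over the tested members of a gene list of the log2 of antibiotic over control. The percentile beside it places that median among 10000 random lists of equal size and similar expression and describes these group values only. Members named where a count was 5 or fewer were named after their values were seen.

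In the antibiotic group SLC6A4, TPH2 and SLC6A3, which mark serotonin and dopamine neurons, were much higher, synaptic vesicle genes were higher as a list, and interferon and microglial genes were lower as lists. The largest finite rise in the authors' deposited table was that of SLC6A4, the serotonin transporter, which went from 0.0965 to 13.1 FPKM (136-fold, q = 0.000336; a log2 of 7.09 that was 6.07 with 0.1 and 3.69 with 1 added to both values). Some peptide genes of the hypothalamus fell, and PMCH, which encodes the precursor of melanin-concentrating hormone, fell from 282 to 18.6 FPKM (15.1-fold, q = 0.000336). The authors had tested 13352 of 16991 features of the deposited table, and 5494 of them (41.1%) changed, 2531 upwards and 2963 downwards. The authors' own significant calls also ask for a 2-fold change, and 984 features met this upwards and 1127 downwards. That balance depended on the scaling of the groups, since multiplying each group to the same upper quartile gave 1174 upwards and 963 downwards.

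Among named genes called significant with a mean of at least 1 FPKM, the 10 largest finite rises in the authors' table were those of SLC6A4, TPH2, TMEM160, SLC6A3, PRPH, NGFR, CCDC85B, GNG7, SLC5A7 and MED9. PRPH, which encodes the neuronal intermediate filament peripherin, rose from 0.284 to 6.78 FPKM (q = 0.000336) in that table. GNG7, a G protein gamma subunit, went from 37.0 to 500.2 FPKM (q = 0.00831), and TMEM160 from 1.93 to 53.7 FPKM (q = 0.000336), per the authors' table. RPRML, U3, NRTN, C19orf12 and 1 of the rows named SOX10 were listed at 0 in the control group and were called significant, so no fold is given for them. The 10 largest falls in the authors' table were those of SCARNA13, SNORD17, TFAM, RNaseP_nuc, CU207250.1, HERC5, ND3, COA5, Metazoa_SRP and RPS27. SNORD17, SCARNA13, RNaseP_nuc and Metazoa_SRP are rows of small structural RNAs, and ND3 is a mitochondrial subunit of respiratory complex I. The rows of CCDC85B, MED9, SCARNA13 and HERC5 overlap another row of the table, so reads from the shared stretch cannot be assigned to one of them from the deposited values. The same holds for the rows used below for DDC, SLC18A2, CXCL10, P2RY12, SOX10, GPR17, ASPA, ERMN, DIO2, KCNJ13, CCDC153, RPL35, ALAS2 and GNRHR.

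Some genes of serotonin and dopamine neurons had the strongest rises. TPH2, the enzyme that starts serotonin synthesis in neurons, went from 0.329 to 18.0 FPKM (54.9-fold, q = 0.000336), and SLC6A3, the dopamine transporter, from 0.390 to 9.57 FPKM (24.5-fold, q = 0.000336) in the authors' table. DDC, the decarboxylase that completes the synthesis of both transmitters, rose 6.87-fold to 18.9 FPKM (q = 0.000336) in that table. HDC, which makes histamine, fell from 20.5 to 5.66 FPKM (q = 0.000336). SLC18A2, the vesicular monoamine transporter, stood at 6.71 FPKM in control and 8.19 in antibiotic (q = 0.811), and MAOA at 77.4 and 64.5 (q = 0.196), in the authors' table. Of the 16 tested members of the list for monoamine synthesis, transport and breakdown, 7 rose, 2 (HDC and HNMT, which inactivates histamine) fell and 7 did not pass, with a median log2 of 0.26 (percentile 91.4). In the deposited table SLC6A4 lies at chromosome 12, 48106435 to 48148808, TPH2 at chromosome 5, 38620464 to 38716998, and SLC6A3 at chromosome 16, 85853596 to 85887788. The submitters' processing notes list the pig build susScr3 but do not tie these coordinates to it. Beside these rises, a list of midbrain and raphe transcription factors, written after the table was first read, had a median log2 of 0.84 over 11 tested members (percentile 99.3). GATA3, PAX5 and TAL1 rose, 8 did not pass, and the 3 members with 5 FPKM in a group had a median log2 of 0.37 (percentile 65.9). Of its 17 matched members 6 reached 1 FPKM in the control group, and the most abundant, NKX2-2, stood at 14.5 FPKM in control and 16.9 in antibiotic (q = 0.473) in the authors' table.

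Receptors for serotonin, dopamine, noradrenaline and histamine were also higher as a list. Of 15 members tested by the authors 6 rose, 1 fell and 8 did not pass, with a median log2 of 0.70 (percentile 98.3). ADRB1 rose 4.24-fold to 1.15 FPKM (q = 0.00896), ADRA1B rose 2.34-fold to 6.82 FPKM (q = 0.000625), and ADRA2A fell 1.84-fold to 3.62 FPKM (q = 0.0025), per the authors' table. Most of these receptors were near the floor of the table, and among the 4 that reached 5 FPKM in a group the median log2 was 0.20 (percentile 65.3). Of 11 tested genes for acetylcholine signalling 5 rose, 1 fell and 5 did not pass, with a median log2 of 0.58 (percentile 94.97). SLC5A7, the choline transporter of cholinergic neurons, rose 8.72-fold to 6.74 FPKM (q = 0.000336), and CHAT, which makes acetylcholine, went from 0.106 to 1.11 FPKM (q = 0.0285) in the authors' table. The nicotinic receptor gene CHRNB2 rose 3.01-fold (q = 0.000336), and BCHE, a cholinesterase, fell 2.46-fold (q = 0.000336), per the authors' table, in which CHRNA2 and ACHE also rose.

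**Figure D1:**
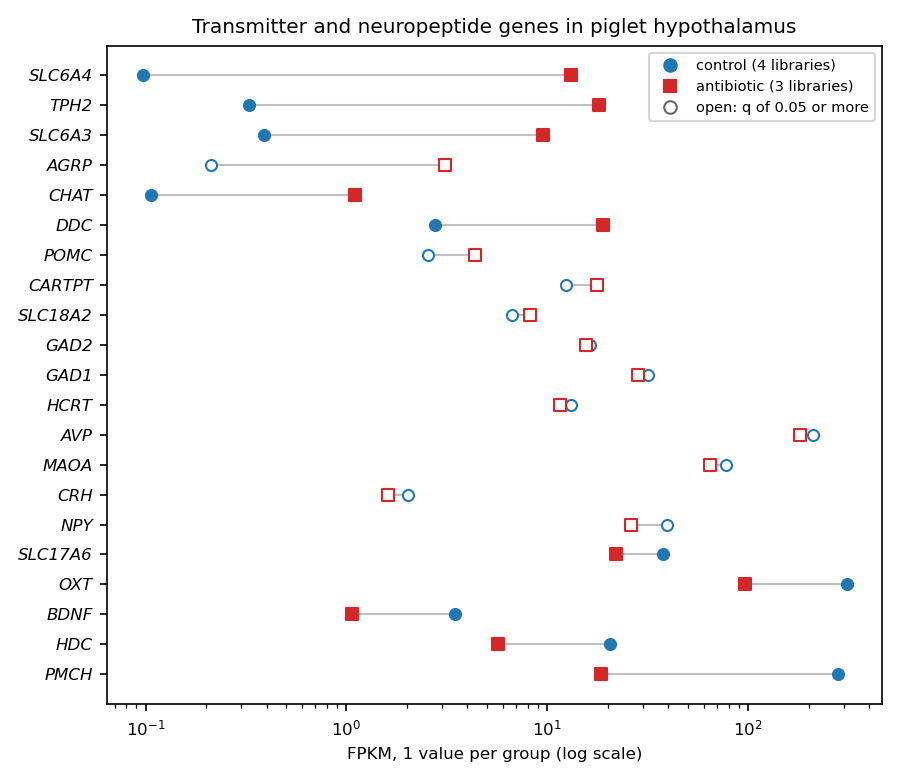
Each row is a transmitter or neuropeptide gene from those fixed in advance, and the horizontal axis is FPKM on a log scale, with circles for the control group (1 value from 4 libraries), squares for the antibiotic group (1 value from 3 libraries) and open symbols where the authors' q was 0.05 or more. SLC6A4, TPH2 and SLC6A3 lie under 1 FPKM in control and at 13.1, 18.0 and 9.57 in antibiotic, while PMCH lies at 282 and 18.6.

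Genes for the amino acid transmitters changed in both directions. Of 24 tested genes for GABA and glycine signalling 7 rose, 7 fell and 10 did not pass in the authors' table, with a median log2 of -0.12 (percentile 36.7). The GABA-A receptor subunit gene GABRD rose 3.63-fold to 30.9 FPKM (q = 0.000336), while GABRA3 fell 2.71-fold to 39.9 FPKM (q = 0.000336), per the authors' table. SLC32A1, the vesicular GABA transporter, rose 2.21-fold (q = 0.000336), whereas the GABA-making enzymes GAD1 and GAD2 stood at 31.7 and 16.4 FPKM in control and 28.2 and 15.6 in antibiotic (q = 0.422 and 0.755). Of 30 tested genes for glutamate signalling 10 rose, 4 fell and 16 did not pass, with a median log2 of 0.36 (percentile 98.6). The metabotropic receptor gene GRM4 rose 3.92-fold (q = 0.000336), and SLC17A6, the vesicular glutamate transporter common in the hypothalamus, fell from 37.5 to 22.1 FPKM (q = 0.000336) in the authors' table. The other falls were those of the receptor genes GRIA4 and GRIA2 and of HOMER1. Among the 21 glutamate genes that reached 5 FPKM in a group, the median log2 was -0.01 (percentile 66.6). Synaptic vesicle and exocytosis genes were higher as a list, and of 25 tested members 12 rose, 3 fell and 10 did not pass, with a median log2 of 0.47 (percentile 99.86). The 3 that fell were RIMS1, RIMS2 and PCLO, which organise the release site. The random lists were not matched on locus length. Tested loci over 50000 bases had 601 rises, 1095 falls and a median log2 of -0.15. Those over 2000 to 5000 bases had 215 rises, 202 falls and a median of 0.15. Whether locus length moved the vesicle list was not tested. SYT2, a calcium sensor of fast release, rose 5.64-fold to 14.4 FPKM, CPLX1 rose 3.51-fold to 80.4 FPKM and SYP, the vesicle protein synaptophysin, rose 2.59-fold to 237.8 FPKM, each with q = 0.000336 in the authors' table.

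Several peptide genes that mark hypothalamic neurons fell. OXT, the oxytocin gene, fell from 310.1 to 96.8 FPKM (q = 0.000336) alongside PMCH in the authors' table, and NUCB2, the precursor of nesfatin, fell 2.61-fold (q = 0.000336). PENK, the enkephalin precursor, and CHGA, a protein of secretory granules, were the 2 members that rose, PENK from 4.97 to 29.4 FPKM and CHGA from 35.7 to 73.4 (both q = 0.000336 in the authors' table). Of 27 tested neuropeptide genes 7 fell and 18 did not pass, with a median log2 of -0.27 (percentile 14.6). NPY stood at 39.5 FPKM in control and 26.0 in antibiotic (q = 0.0513), POMC at 2.55 and 4.34 (q = 0.0938), AGRP at 0.211 and 3.09 (q = 0.302) and CARTPT at 12.4 and 17.8 (q = 0.0952) in the authors' table. CRH, AVP and HCRT did not pass either, with q of 0.659, 0.461 and 0.566.

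Receptors for feeding and stress hormones showed 5 falls and no rise among 23 tested members of the authors' table, with a median log2 of 0.26 (percentile 83.3). Among them were NR3C1, the glucocorticoid receptor, SSTR2, TACR3 and NPY1R, and NR3C1 went from 16.4 to 10.2 FPKM (q = 0.00138). Transcription factors that mark hypothalamic regions were lower as a list, since of 10 tested members 5 fell, 2 rose and 3 did not pass, with a median log2 of -0.58 (percentile 1.91). In the authors' table FEZF1 fell 7.72-fold (q = 0.000625) and DLX1 fell from 6.05 to 1.21 FPKM (q = 0.000336), while LHX9 rose 2.26-fold (q = 0.000625). ISL1 and LHX1 also fell, and IRX3 also rose. Only 3 of these genes reached 5 FPKM in a group, and their median log2 was -0.19 (percentile 40.55). A row named TTF1 on chromosome 7, chosen after its values were seen, fell from 6.14 to 0.838 FPKM (q = 0.000336), and TTF1 is also a synonym of NKX2-1, a regulator of the hypothalamus. The other row named TTF1, on chromosome 1, stood at 1.56 and 1.99 FPKM (q = 0.459) in the authors' table.

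Growth factor and activity genes gave a mixed picture. BDNF, a neurotrophin, fell from 3.45 to 1.06 FPKM (q = 0.000336), while CRTC1, a coactivator of the transcription factor CREB, rose 2.54-fold (q = 0.000336) in the authors' table. Of 13 tested genes for neurotrophins and CREB 6 rose, 2 (BDNF and its receptor gene NTRK2) fell and 5 did not pass, with a median log2 of 0.47 (percentile 96.5). Of 14 tested immediate early genes, which respond within minutes to neuronal activity, 6 fell, none rose and 8 did not pass, with a median log2 of -0.46 (percentile 3.89). FOS fell from 13.2 to 3.06 FPKM (q = 0.000336) and EGR1 fell 1.86-fold (q = 0.00291), per the authors' table. Of 12 tested genes for large neutral amino acid transport 5 rose, none fell and 7 did not pass, with a median log2 of 0.42 (percentile 94.4), and SLC38A5, a glutamine carrier, rose 2.03-fold (q = 0.000336 in the authors' table) along with SLC38A3, SLC6A17, SLC43A2 and SLC7A1. SLC7A5, TH and CREB1 had no matched row and are not analysed here. A row named CREB, paired in the file with an ID that the gene name table gives to ATF1 and chosen after its values were seen, fell from 12.1 to 6.75 FPKM (q = 0.00138), and the other row of that name stood at 9.99 and 5.03 FPKM (q = 0.0908) in the authors' table. Of 7 tested genes of the kynurenine pathway, which degrades tryptophan, 4 fell, 1 rose and 2 did not pass, with a median log2 of -0.70 (percentile 3.98). The 4 were KYNU, KMO, AHR and IDO1, and KMO fell from 8.34 to 4.24 FPKM (q = 0.0166) in the authors' table, while GOT2 rose 1.60-fold (q = 0.00312). Over the 4 members with 5 FPKM in a group the median log2 was 0.41 (percentile 85.85).

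Antiviral and microglial genes were lower as lists. Of 30 tested interferon response genes 18 fell, none rose and 12 did not pass, and the median log2 of -0.95 lay below those of all 10000 random lists. HERC5, an interferon-induced ligase, fell from 676 to 24.7 FPKM, IFI44L from 68.9 to 19.9 and B2M, the light chain of MHC class I, from 369 to 110.8, each with q = 0.000336 in the authors' table. HERC5 and B2M have more than 1 row in the table, and the row with the highest mean was used. Of 24 tested genes for inflammatory cytokines and NF-kB 8 fell, 3 rose and 13 did not pass, with a median log2 of -0.38 (percentile 3.18). The chemokine genes CCL2, CXCL10 and CCL5 fell 3.44-fold, 3.08-fold and 2.35-fold (each q = 0.000336 in the authors' table), and the 3 that rose were NFKB2, TGFB1 and RELA. Microglia and macrophage markers moved with them, since 11 of 19 tested members fell, 1 rose and 7 did not pass, with a median log2 of -0.68 (percentile 0.52). P2RY12, a receptor of resting microglia, fell from 99.97 to 43.5 FPKM and C1QA fell 2.72-fold, while TREM2 rose 3.43-fold, each with q = 0.000336 in the authors' table.

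Chaperone, ribosomal and respiratory genes were also measured as lists. Of 19 tested genes for heat shock and endoplasmic reticulum stress 8 fell, none rose and 11 did not pass, with a median log2 of -0.34 (percentile 25.4; -0.04 after quantile normalization), and HSPH1, a large chaperone, fell from 403 to 136 FPKM (q = 0.000336) in the authors' table. Of 45 tested genes for cytosolic ribosomal proteins 22 fell, 5 rose and 18 did not pass, with a median log2 of -0.30 (percentile 43.3), and the rises were those of RPL13, RPS15, RPL35, RPL7A and RPLP2. After quantile normalization the median was 0.33 (percentile 90.8), so its direction depended on the scaling. RPS21 fell 5.49-fold (q = 0.000336 in the authors' table), and these genes have many processed copies in the genome with which reads can be shared. Of 41 tested genes for the nuclear-encoded respiratory chain 6 rose, 8 fell and 27 did not pass, with a median log2 of -0.02 (percentile 88.0; 0.27 after quantile normalization), and NDUFB6 fell 2.41-fold while NDUFV1 rose 1.81-fold (both q = 0.000336). The mitochondrial gene ND3 alone held 17.0% of the summed control FPKM of the authors' table and fell 19.7-fold (q = 0.000336), a log2 of -4.30 that became -0.65 after quantile normalization. Mitochondrial rows made up 22.1% of the summed FPKM in control and 5.94% in antibiotic. ND3 held 209838 of their 272439 FPKM in control and 10646 of 33471.7 in antibiotic, so most of this drop came from that 1 row. The shares are of unlike totals, since the summed FPKM was 1.23e+06 in control and 563424 in antibiotic. In antibiotic 1 row, which was not mitochondrial, held 20.6% of the sum.

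Markers of the other cell types in a hypothalamus block moved in different directions. Of 12 tested genes of astrocytes and tanycytes 5 rose, 2 fell and 5 did not pass, with a median log2 of 0.28 (percentile 94.4), and FGFR3 rose 6.09-fold to 37.2 FPKM while VIM fell 1.72-fold (both q = 0.000336 in the authors' table). ALDOC, GFAP, DIO2 and SLC1A2 also rose, and AQP4, the water channel, also fell. Of 17 tested genes of oligodendrocytes and myelin 3 rose, 5 fell and 9 did not pass, with a median log2 of 0.03 (percentile 85.8; 0.30 after quantile normalization), and UGT8 fell 2.07-fold while CNP rose 1.90-fold (both q = 0.000336 in the authors' table). MYRF and MAG also rose, and ASPA, ERMN, TSPAN2 and ENPP2 also fell. Of 9 tested genes of oligodendrocyte precursors 5 rose, none fell and 4 did not pass, with a median log2 of 0.61 (percentile 98.4; percentile 97.4 over the 8 genes with 5 FPKM in a group). These 5 were OLIG1, SOX10, CSPG4, C1QL1 and GPR17, and the SOX10 row with the higher mean rose from 4.93 to 23.7 FPKM (q = 0.000336) in the authors' table. Of 22 tested genes of blood vessels and pericytes 6 rose, 6 fell and 10 did not pass, with a median log2 of 0.06 (percentile 72.4). COL1A1, a collagen of connective tissue, fell from 619 to 46.1 FPKM, while VWF, made by endothelium, rose 4.09-fold (both q = 0.000336 in the authors' table).

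Choroid plexus genes were lower as a list, and the beta globin gene fell. Of 11 tested genes of ependyma and choroid plexus 5 fell, 1 rose and 5 did not pass, with a median log2 of -0.69 (percentile 1.36), and the list stood at percentile 40.9 when only its 7 genes with 5 FPKM in a group were kept. TTR, the transthyretin gene of choroid plexus, fell from 289 to 70.6 FPKM (q = 0.000336), and FOXJ1, a regulator of cilia, rose 3.96-fold (q = 0.000891), per the authors' table, in which CLIC6, KCNJ13, KL and CCDC153 also fell. Of 4 tested blood genes HBB, the beta globin gene, fell from 5400.1 to 386 FPKM and CD2 fell 3.43-fold (both q = 0.000336), while CD3E and ALAS2 did not pass, with a median log2 of -0.95 (percentile 2.53), or -0.42 (percentile 17.25) over 9 genes with untested ones kept. Of 9 tested genes of thalamus, cortex and striatum neurons 5 rose, none fell and 4 did not pass, with a median log2 of 0.57 (percentile 96.6), which became -0.07 (percentile 55.45) over the 7 with 5 FPKM in a group and 0.03 (percentile 57.05) with untested genes kept. The 5 were CALB2, LEF1, SLC17A7, PPP1R1B and ADORA2A, and CALB2 went from 134.8 to 219.2 FPKM (q = 0.00114) in the authors' table. Of the anterior pituitary list, 2 genes were tested, of which GNRHR fell 3.04-fold (q = 0.0267) and LHB did not pass (q = 0.808).

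**Figure D2:**
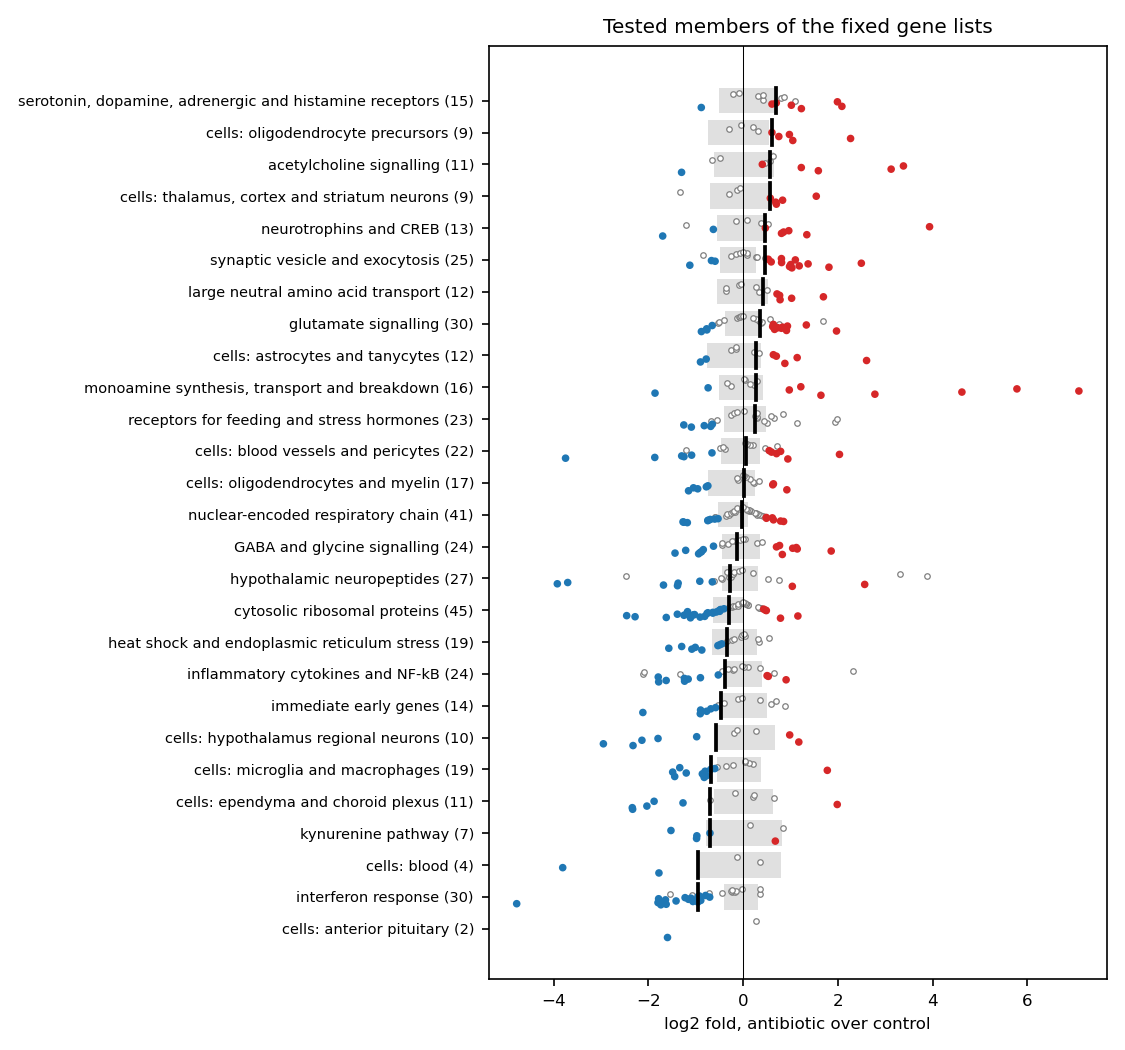
The horizontal axis is the log2 fold of antibiotic over control for each tested gene of the 27 lists, with filled red points for genes that rose, filled blue points for genes that fell and open points for genes that did not pass. Numbers in brackets give the tested genes, black bars the list medians and grey bands the central 95% of 10000 random lists; PROK2, listed at 0 in control, is not drawn. The interferon list has the lowest median, -0.95, outside its band, and the anterior pituitary list has too few tested genes for a median.

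Of the 26 lists with enough tested genes for a median, 8 lay outside the central 95% of their random lists, 4 above and 4 below. Chance alone would give 1.3 if the lists, and the genes within each list, were independent. Adjusted over the list alone, the counts of rises and falls were the same in 20 lists. They became 7 and 1 for the monoamine and histamine receptors, 7 and 8 for GABA and glycine, 6 and 3 for neurotrophins and CREB, 0 and 9 for heat shock, 6 and 22 for ribosomal proteins, 6 and 7 for blood vessels, and 1 and 6 for ependyma and choroid plexus. Because the authors' deposited table has 1 value per group, it cannot show how many of the 3 antibiotic and 4 control libraries carry any of these differences.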

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

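The alternatives with pseudocount 0.5, at least 1 FPKM in both groups, a recomputed adjustment, and without short or overlapping rows were chosen after seeing the data, as were those for lists other than the filters and trimmed mean scaling. The authors' q was kept under each scaling and pseudocount, so these could move only folds and, for the scalings, directions. Among 695 values of 139 named rows under 5 settings of scaling and pseudocount, no gene past the authors' q changed sign. Of those that did not pass, AVP went from -0.22 to 0.14 after quantile normalization and GAD2 from -0.07 to 0.01 after upper quartile scaling. For the pseudocounts a kept sign was fixed in advance, since the same amount added to both values cannot turn a fold. Upper quartile and trimmed mean scaling shift every log2 by the same small amount. They moved the median log2 of tested rows from -0.03 to 0.05 and 0.01. Only quantile normalization could have turned larger folds. Quantile normalization moved ND3 from a log2 of -4.30 to -0.65, RPS3 from -1.39 to -0.55, RPL26 from -1.62 to -0.94, RPS21 from -2.46 to -1.47, RPS27 from -4.13 to -3.08, HBB from -3.81 to -2.90 and ALDOC from 0.88 to 1.98. With log2(value + 1) SLC6A4 went from 7.09 to 3.69 (6.07 with 0.1 added), TPH2 from 5.78 to 3.84, SLC6A3 from 4.62 to 2.93 and CHAT from 3.38 to 0.93. The count of 2-fold calls, 2111 as deposited, lay between 1614 and 2143 under the other settings but fell to 1394 with log2(value + 1), which by construction shrinks the folds of low genes. Scaling turned the majority of these calls: 1174 rose and 963 fell after upper quartile scaling, 1082 and 1042 after trimmed mean scaling, and 1132 and 1011 after quantile normalization. At a q of 0.01 there were 800 rises and 957 falls.

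Of the 26 lists with a percentile 8 stood outside the central 95% of random lists, and between 7 and 10 did under the other settings, except for 4 with at least 5 FPKM in 1 group, which left fewer genes to test. With that filter interferon, microglia and synaptic vesicle genes stayed outside, neurotrophins and CREB joined them at percentile 97.8, and the lists of glutamate, monoamine and histamine receptors, oligodendrocyte precursors, choroid plexus and hypothalamic regions did not. The receptors (percentile 95.8) and choroid plexus (3.35) also lay inside with untested genes kept, choroid plexus (10.1) and oligodendrocyte precursors (97.2) with log2(value + 1), and oligodendrocyte precursors (97.1) and hypothalamic regions (3.55) against random lists not matched on expression. Blood genes, inside at percentile 2.53 as deposited, lay outside under 4 settings and inside at 17.25 (9 genes, median -0.42) with untested genes kept. Inflammatory cytokines joined after quantile normalization (1.65), the thalamus, cortex and striatum list (98.35) and neurotrophins (97.6) with log2(value + 1), and the anterior pituitary with untested genes kept (8 genes, median -2.41, below all random lists). No paired analysis was possible because the deposited table has 1 value per group and no library columns. For the same reason leaving out each replicate, array weights, camera and fry were not run, nor were the count-based tools and factors, since no counts were used here. Library depth is unknown, so no limit for values listed at 0 is given.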

Other observations

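Among the KEGG terms of the deposited table, genes of calcium signaling stood highest and genes of p53 signaling lowest by percentile among random lists. Of 61 tested calcium signaling genes 21 rose and 5 fell in the authors' table, with a median log2 of 0.41 (percentile 99.96). The calcium channel gene CACNA1G rose from 5.34 to 15.9 FPKM and STIM1, a sensor of stored calcium whose row overlaps another, from 9.71 to 18.8 (both q = 0.000336), while CAMK2D fell from 74.6 to 36.1 (q = 0.000336). Of 30 insulin secretion genes 14 rose and 2 fell (percentile 99.93), and of 56 thyroid hormone signaling genes 22 rose and 3 fell (percentile 99.8). Of 26 p53 signaling genes 1 rose and 12 fell, with a median log2 of -0.59 (percentile 0.11). CCNG1 fell from 64.1 to 41.6 FPKM (q = 0.000336), the mitotic cyclin CCNB1 from 1.75 to 0.676 (q = 0.00524) and CYCS, the cytochrome c gene, from 149.3 to 77.4 (q = 0.000336) in the authors' table. Of 42 cell cycle genes 4 rose and 13 fell (percentile 1.94). The terms share members and were read from the same table after its values were seen. Of 191 terms 40 lay outside the central 95% of random lists, where 9.55 would by chance if terms and genes were independent.

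In the patterns weighed below, all tests were chosen after the pattern had been seen. The tests of the midbrain list and of short rows were set down before their own values were looked at, and the others after.

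SLC6A4, TPH2, SLC6A3 and SLC5A7 rose while PMCH, OXT and HDC fell, although the monoamine, acetylcholine and neuropeptide lists as wholes lay inside the central 95% of random lists. A change of transmitter genes in blocks of equal regional makeup would leave hypothalamic transcription factors in place; their median log2 was -0.58 (percentile 1.91), but -0.19 (percentile 40.55) over the 3 with 5 FPKM in a group and percentile 3.55 against unmatched lists, so it cannot be told apart, although 15 of 18 matched members were lower and the median was -0.96, below all random lists, with untested genes kept. A candidate explanation is more midbrain in the antibiotic blocks, because the tested midbrain and raphe regulators had a median log2 of 0.84 (percentile 99.3), with GATA3, PAX5 and TAL1 rising and 8 of 11 not past q, among them NKX2-2 (q = 0.473), and 0.37 (percentile 65.9) over the 3 with 5 FPKM, while all 17 matched members had the higher value in antibiotic and the median was 1.39, above all random lists, over 15 with untested genes kept. The transporter SLC18A2, which these neurons also need, was 6.71 and 8.19 FPKM (q = 0.811), which more midbrain tissue alone leaves unaccounted for unless fewer histamine neurons, whose gene HDC fell, offset it. The SLC18A2 row overlaps another, and reads of the shared stretch cannot be assigned, so its value cannot decide this. With 2 FPKM columns in the table, 1 per group, a few libraries with differently placed blocks cannot be told apart from a difference in every animal, and an effect of the antibiotics on these genes stays open.

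Interferon response genes were lower as a list, with 18 of 30 falling, 12 not past q and no rise. A lower share of microglia alone would lower both lists alike, and the median log2 of interferon genes was -0.27 from that of microglia genes, with a bootstrap 95% interval over genes of -0.84 to 0.06, so this cannot be told apart from a separate antiviral difference. One or a few control animals with an antiviral response could give the same values, and the 2 FPKM columns, 1 per group, cannot show it. A lower antiviral tone after antibiotics stays open as a hypothesis that was not tested here.

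Features with short loci were lower, since of 37 tested rows with loci of 500 bases or less 17 fell, 4 rose and 16 did not pass. Of 10 tested small structural RNAs with loci of 500 bases or less the median log2 was -4.18, and a lower yield of these RNAs alone would leave other short rows in place. The 27 tested short rows of other kinds had a median log2 of -1.31, below all 10000 sets of random rows, with 11 falls and 3 rises, which argues against small RNAs as the whole cause. A yield or scaling effect tied to transcript length could give the same value. ND3, with a locus from 10652 to 10998, is itself a short row, so this value is no separate evidence about ND3. Whether such an effect touched ND3 was not tested. At 500 to 1000 bases the median was -0.11, but loci include introns, so longer loci say little about transcript length. GC content and the authors' length correction were not tested here, and no biological explanation was tested.

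A list of hindbrain and motor neuron genes had 6 tested members, of which RET and SLC10A4 rose and CALCB fell from 201 to 45.1 FPKM (q = 0.000336 in the authors' table), with a median log2 of 0.63 (percentile 96.8). HOXA3, HOXA5, HOXB3 and PHOX2A were under 0.1 FPKM in both groups.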
